A study of Bos taurus with 2 samples.

How the data were processed

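Cells of day 25 bovine chimeric embryos were dissociated with papain, sorted and loaded on the 10x Genomics Chromium 3′ v3.1 platform, per the labels' protocols. The sort gate is not given in the sources used here. The authors deposited raw UMI counts for 17846 genes in 4437 barcodes, of which 499 genes had no count in any barcode. Cell Ranger, R 4.1.2, Seurat 4.3.0 and the genome build bosTau9 were named per the submitters' processing notes, with no Cell Ranger version. Barcodes in the deposited counts had at least 504 UMI, at most 3999 genes and at most 4.98% mitochondrial counts, and the filter behind these limits is not given in the sources used here. Columns were tied to libraries by the number in their prefix, which matches the replicate number of the sample titles, and 0 columns of other samples were left out. Gene names were used as the deposited table gives them, and no coordinates were used. XIST was not analysed here.

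Cells were kept with at least 500 genes, at least 1000 UMI and at most 15% mitochondrial counts, which left 1843 and 2316. The mitochondrial limit removed none. Scrublet called 1 and 6 doublets, 0.168% of cells, so doublet calling removed very little, and doublets remain possible in every unit. In all, 4152 cells were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1.0, with seed 0 and no batch integration. Clustering left out 9013 held-out genes: 20 lists of genes, GFP and a seeded random 50% of the genes that were no cell type marker. Results between units are given only for held-out genes. The lists, the markers, the tests and the rule for named genes were fixed before the data were examined.

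The rule by which clusters were named was set after the clusters and their marker levels had been seen. A marker counted as detected at 20 CPM or more and at least 25% of its highest level in any cluster, and a name needed at least 3 detected markers. A cluster kept its number where its 10 leading genes held more markers of another class, where over 90% of its cells came from 1 library, or where no list qualified. Names could differ under another rule. One cluster with at least 5 markers of more than 1 class was split again at resolution 0.5 into trophoblast-like cells, cardiomyocyte-like cells and cluster 16c. Shares carry exact Clopper-Pearson 95% intervals, and GFP levels exact Poisson intervals, which cover counting error only.

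Counts were summed per unit and library and fitted with edgeR 4.0.16 (R 4.3.3, glmQLFit robust, TMM, filterByExpr) with library as an additive term. Each unit of at least 20 cells in each library was set against the unweighted mean of the others. In this contrast a gene with no count in another unit cannot be called lower, which was found only after the results had been seen. Per unit, 120.0 to 266 genes with a negative fold change had such a unit, and 0 of them were called. Named falls could be drawn only from the other genes. The fit was kept as planned, and limma-trend on log2 CPM with a prior count of 2 was added as an alternative. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one. Of 152 pairs of list and unit 48 were called at the preset correlation and 3 of these with the estimated one: the matrix list in cluster 9, cluster 6 and neuron-like cells. For each unit the rule named the 6 held-out genes with the largest rise and the 3 with the largest fall among those with adjusted p under 0.05, the same direction in both libraries and at least 50 CPM in the higher arm, leaving out unnamed identifiers. Some genes that the rule named are not reported here. GFP was always named, and members of the lists served as examples of their counts. Ribosomal protein genes were not a fixed list, and their counts were extended to other units after those of neural progenitor-like cells had been seen. The rule did not say how the other units were averaged. An arithmetic mean of CPM was used at first and was replaced, after its results had been seen, by a geometric mean, because the fitted contrast averages on the log scale and the arithmetic mean could carry the opposite sign. Of 54 named rises 52 and of 27 named falls 13 were also named with the arithmetic mean, so the choice of falls rests on this change. Fitted fold changes of genes with few counts depend on the prior count. Where a unit had no count, a bound at a floor of 3 counts over both libraries is given.

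The fit was tested on simulated data drawn from the overall share of each gene, the real library sizes and the fitted dispersions, with genes changed by 2-fold or 4-fold in 1 unit at a time. It recovered 66% of 2-fold and 93% of 4-fold changes in cluster 9, and 94.9% and 100% in neural progenitor-like cells, with 7 and 16 false calls. Over the 8 units false calls ranged from 5 to 24. Only genes above a minimum total count were changed, so the recovery does not cover genes with few counts. All other genes had the same share in every unit. Large differences in composition, and genes absent from a unit of the reference, were therefore not tested.

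Alternatives covered cell filters, doublets kept, resolution 0.5 and 1.5, variable genes from all genes, centring within library, RLE size factors, DESeq2 1.42.0, no count filter, no library term, a minimum of 50 cells and each library left out. Fold changes with 1 library left out are differences of log2 CPM with a prior count of 2, and so lie nearer 0 for genes with few counts. Chosen after seeing the data were a minimum of 5 cells, which also allowed the extraembryonic contrast, limma-trend, cells of at least 3000 UMI and UMI other than globin for GFP, and shares without clusters of almost 1 library.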

Results

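Single-cell RNA was measured in day 25 bovine embryos into which bovine embryonic stem cells had been incorporated, so that each embryo was a chimera. There was 1 group of 2 libraries, replicate 1 and replicate 2. Replicate 1 held 1973 barcodes and 11182089 UMI (unique molecular identifiers, each standing for 1 captured transcript), with a median of 4889 UMI per barcode. Replicate 2 held 2464 barcodes and 15427708 UMI, with a median of 5601. After filters 1842 and 2310 cells were analysed. The labels do not say whether the libraries came from different embryos, so p-values may not cover the spread between embryos. With library as a term in the fit, they measure how differences between units varied between these 2 libraries. That spread had 7 residual degrees of freedom. It was moderated by a spread shared across genes, with a median of 41.2 prior degrees of freedom. All errors are SD over the 2 libraries unless given as SE.

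The first question was which cell types the chimeric embryos contained. Clusters whose best-matching marker list was neural progenitor or neuron predominated, with 94.4% of cells in replicate 1 and 93.2% in replicate 2, a mean of 93.8% ± 0.821 (SD, n = 2). This neural-list group also holds clusters 4, 6, 7, 13, 15 and 18, whose leading genes had more markers of a non-neural class, and cluster 14. Neural progenitor-like cells, named from SOX2, NES and RFX4 with other markers, made up 52.7% and 48.1%. Neuron-like cells, named from ELAVL3, ELAVL4, DCX and ONECUT2, made up 11.4% and 10.5%. Cardiomyocyte-like cells (TNNT2, MYL7, NKX2-5) numbered 14 and 22, and erythroid-like cells (HBZ, HBE1, ALAS2) numbered 9 and 21. Trophoblast cells form the outer layer that becomes the placenta. Trophoblast-like cells (PAG2, PAG8, SSLP1) numbered 7 and 10, or 0.38% (exact 95% interval 0.153 to 0.781) and 0.433% (0.208 to 0.795). Binucleate trophoblast-like cells (CSH2, PRP1, GCM1) numbered 7 and 4. Some small classes changed when each library was clustered alone: no binucleate trophoblast-like cells were named, cardiomyocyte-like cells were 1.09% in replicate 1 and 0% in replicate 2, and trophoblast-like cells 0.760% and 0.390%.

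Other clusters kept a number because their leading genes or libraries did not allow a name. Cluster 9 (34 and 71 cells) was led by COL1A1, APOA1 and COL1A2 and carried 6 of 13 mesenchyme markers. Yet its leading genes held more markers of hepatic or yolk sac endoderm, APOA1 and RBP4, than of mesenchyme, COL3A1 alone. Cluster 6 (73 and 86 cells) carried 7 of 10 neuron markers and was led by CNTN5, NRCAM and HAND2. Cluster 4 (91 and 186 cells) had SHH among its leading genes. Cluster 13 (104 and 117 cells) carried 10 of 10 neural progenitor markers, yet SERPINA1, AHSG, APOA2 and AFP, which encode plasma proteins, led it. Cluster 15 (108 and 210 cells) was led by SPARCL1, RSPO3 and RSPO2, and cluster 7 (113 and 133 cells) by PF4 and TFF2. Clusters 14 and 18 each held 68 cells of 1 library and 1 cell of the other. Clusters 16c (15 and 17 cells) and 19 (17 and 11 cells) matched no single list. The cells were sorted before loading by a gate that the labels do not describe, which can set these shares and, if it used GFP, the GFP levels below. With all deposited barcodes the share of the neural-list group was 85.2%, and neural progenitor-like cells ranged from 45.7% to 70.2% over the alternatives. Neuron-like cells fell to 4.44% when genes were centred within each library.

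**Figure D1:**
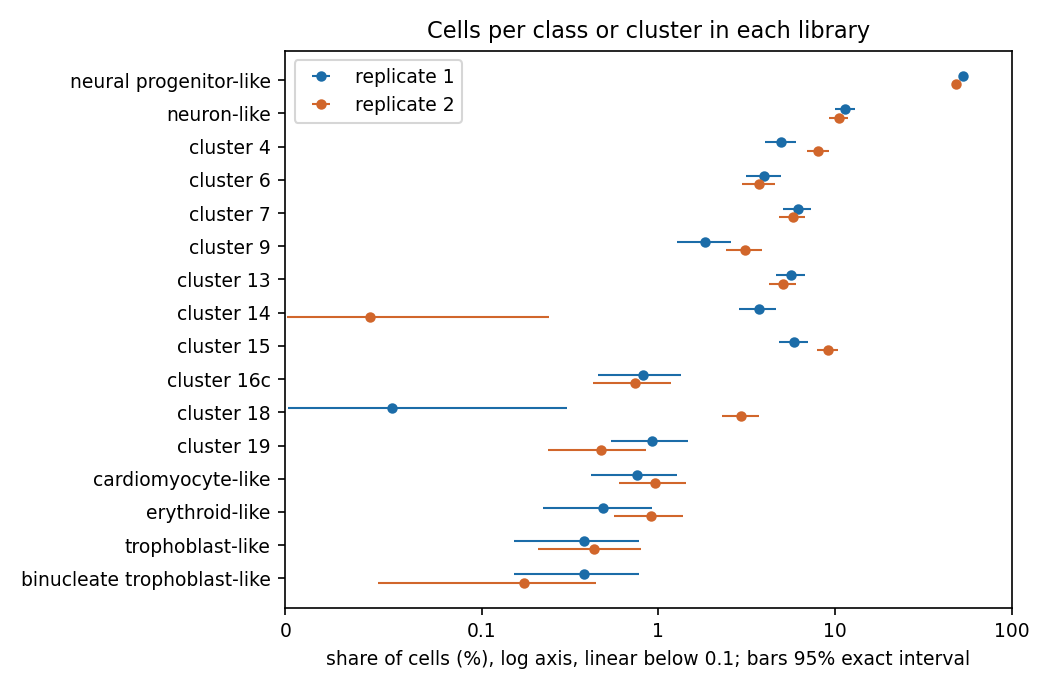
Share of cells (%, log axis that is linear below 0.1) of each class or numbered cluster, with a point per library and bars for the exact 95% interval. Neural progenitor-like cells lie near 50.4% in both libraries, while clusters 14 and 18 each lie almost wholly in 1 library.

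GFP, the green fluorescent protein reporter, has a row in the count table, and its level differed greatly between classes and clusters. Neural progenitor-like cells had 1217 and 1544 CPM (UMI of the gene scaled to the same total in each unit) in the 2 libraries and neuron-like cells 1378 and 1584 CPM, while the whole neural-list group had 1774 and 2020 CPM. The highest level of any tested unit was in cluster 4, at 5156 and 3774 CPM, followed by cluster 15 at 2435 and 2654 CPM. Cluster 9 had 57.1 and 47.1 CPM, trophoblast-like cells 52.8 and 27.9 CPM, and erythroid-like cells 44.2 and 25.9 CPM. Binucleate trophoblast-like cells had 31.1 CPM in replicate 1 and no GFP UMI in 4 cells of replicate 2, which allows up to 153 CPM (exact Poisson bound). Cardiomyocyte-like cells differed between libraries, with 1982 CPM in 14 cells of replicate 1 and 252 CPM in 22 cells of replicate 2. A GFP UMI was found in 78.6% and 45.5% of these cells, but the top 3 cells held 62.7% of 276 GFP UMI in replicate 1 and 83.0% of 53 in replicate 2. Within the neural progenitor-like class the clusters ranged from 354 CPM ± 91.4 (SD, n = 2) in cluster 8 to 4478 ± 407 in cluster 12. The neuron-like class joined cluster 5, at 446 ± 2.19, and cluster 10, at 2464 ± 286, so its pooled level describes neither. In both classes the cluster with more GFP was deeper. Median UMI per cell was 3718 and 8808 in clusters 8 and 12, and 4196 and 8992 in clusters 5 and 10. Cluster 3 went the other way, at 1837 CPM and 4510.5 UMI against 872 CPM and 5875.5 UMI in cluster 1. GFP differences among neural-list clusters were not separated from depth.

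A GFP UMI was found in 75.3% and 73.8% of neural progenitor-like cells, 72.4% and 74.4% of neuron-like cells and 79.9% and 80.9% of the neural-list group, at a median of 4470.5, 5837 and 5443 UMI per cell. The share was 47.1% and 40.8% in cluster 9, at a median of 12104 UMI, 5 of 7 and 3 of 10 in trophoblast-like cells, at a median of 12550.0 UMI, and 66.7% and 52.4% in erythroid-like cells, at a median of 25821.5 UMI. After each cell was thinned to 2000 UMI the shares were 59.7% and 59.6% in neural progenitor-like cells, 68.3% and 71.0% in the neural-list group, 6.25% and 7.81% in cluster 9, 28.6% and 22.2% in trophoblast-like cells and 11.1% and 5.00% in erythroid-like cells. Thinning left out 182 and 200 cells of the neural-list group that were shallower. No cell type of a chimera is sure to lack GFP, so no level here is a known background. Globin, counted here as HBZ, HBE1 and HBE4, made up 48.5% and 49.97% of UMI in erythroid-like cells. Other globin genes, among them HBE2 and HBM, were not counted. Without the counted globin, GFP in erythroid-like cells stood at 85.7 and 51.7 CPM, from 10 and 14 GFP UMI. The thinned shares of erythroid-like cells are lowered by globin too. In the fit across units, GFP was higher in cluster 4 than in the mean of the other units (log2 fold change 2.37, SE 0.13, edgeR adjusted p = 6.2e-21) and lower in cluster 9 (log2 fold change -4.44, SE 0.25, adjusted p = 4.6e-21), each in 2 of 2 libraries. The contrasts of neural progenitor-like cells (log2 fold change -0.08, adjusted p = 0.65), neuron-like cells (0.34, adjusted p = 0.049) and cluster 6 (0.57, adjusted p = 0.0013) turned direction under another set of units. With units of at least 5 cells per library clusters 4, 9, 13 and 15 kept their direction and call, at 3.46, -2.95, 2.21 and 2.57 against 2.37, -4.44, 1.05 and 1.44. With units of at least 50 cells clusters 4, 13 and 15 stood at 1.79, 0.45 (adjusted p = 0.011) and 0.83, and cluster 9 had too few cells. The lower level in cluster 7 (-1.25, adjusted p = 2.1e-08) lost its call, at -0.10, when units of at least 5 cells per library entered the fit.

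**Figure D2:**
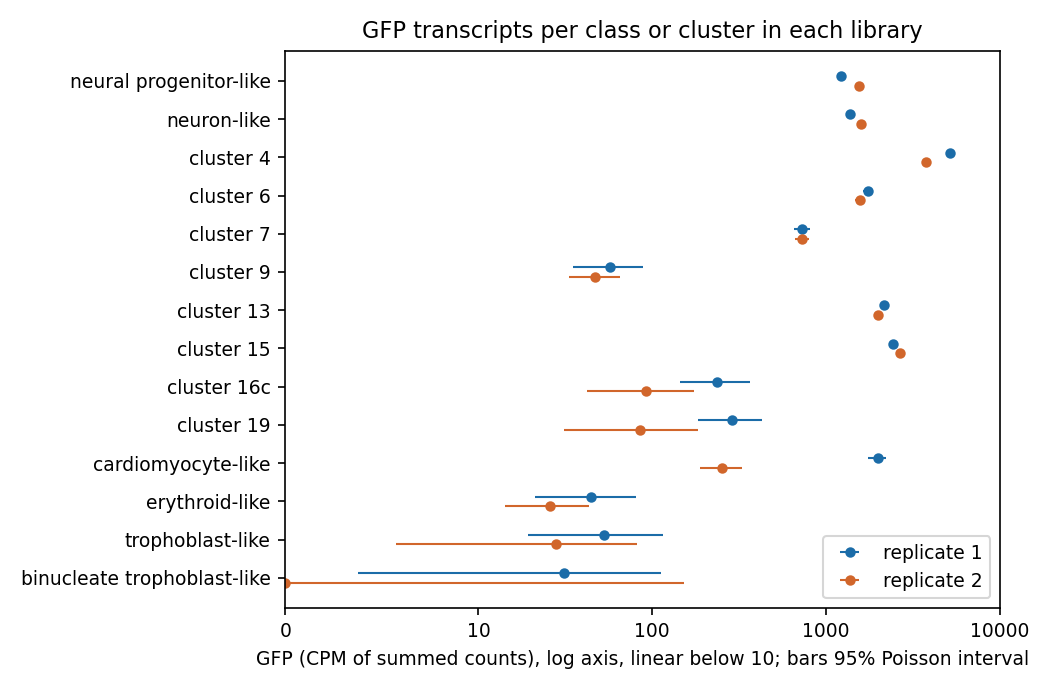
GFP level (CPM of summed counts, log axis that is linear below 10) per class or numbered cluster, with a point per library and bars for the 95% Poisson interval, which covers counting error only. Cluster 4 lies at 3774 CPM or more in both libraries, and cluster 9, erythroid-like and trophoblast-like cells lie below 60 CPM.

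The next question was how each unit differed from the others in genes that had no part in the clustering. The units were made by clustering these same cells, and held-out genes can vary together with the clustering genes. Differences were therefore likely from the outset, and the p-values do not measure how distinct the units are. Some genes below, such as COL1A1 in cluster 9, are also leading genes of their cluster. Of the held-out genes 5913 were tested in 8 units of at least 20 cells per library. Levels below are CPM with TMM factors, and the level of the other units is their geometric mean. Calls are by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. A gene with no count in a unit of the reference could not be called lower, because the mean of the reference then has no lower bound. Such a unit existed for 537 of the 5913 genes, so counts of lower genes below are incomplete. By limma-trend, which has no such limit and was added after seeing the data, all 81 named genes kept their calls. These genes had the largest folds and the named falls were free of the limit, so their calls do not test it. Among all called genes, those also called by limma-trend ranged from 2675 of 4071 in neural progenitor-like cells to 3146 of 3181 in cluster 9.

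Cluster 9 stood apart by its extracellular matrix. COL1A1, a chain of fibrillar collagen, stood at 16466 CPM ± 618 (SD, n = 2) against 18 in the other units (log2 fold change 9.82, SE 0.14, adjusted p = 1.6e-46). COL6A1, another collagen chain, stood at 962 ± 68.7 against 0.997. Of 28 tested members of the collagen and matrix list 24 were higher and 3 lower, with the same counts adjusted over the list alone, and the list stood apart from other genes by camera (adjusted p = 1.6e-09 at the preset correlation, adjusted p = 0.021 with an estimated correlation). The largest rises also included the water channel AQP1 (1128 CPM against 0.723), KLK1 (2995 against 2.07), A2M, a protease inhibitor (2839.8 against 2.73), and the transcription factor FLI1 (143 against 0.235), whose call was lost with DESeq2 (adjusted p = 0.080). No count was found for CDH6, DZANK1 and PHACTR1, which puts them at least 23.3-fold, 19.8-fold and 17.4-fold lower at a floor of 3 counts over both libraries.

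HOX genes, which mark position along the body axis, separated cluster 9 further. All 5 tested central HOX genes and both tested posterior ones were higher there, as was also found adjusted over the list alone. HOXC8 stood at 64.6 CPM ± 14.3 against 0.111, HOXB8 at 58.8 ± 11.8 against 0.313 and HOXB9 at 40.2 ± 8.35 against 0.0844. None of these 7 genes was called higher in any other unit, and each had no count in at least 2 of them, so no fall could be called. The camera call for the central genes was lost with an estimated correlation (adjusted p = 0.12). Of 15 imprinted genes 9 were higher and 2 lower, also adjusted over the list alone, without a camera call (adjusted p = 0.057): the growth factor IGF2 stood at 2091 CPM ± 25.4 against 49.6, and PLAGL1 was lower at 12.4 against 206. APOE stood at 9629 CPM ± 1939 against 67.8. Early-response genes moved with these groups: 13 of 16 stress and dissociation genes were higher and 2 lower, also adjusted over the list alone, among them FOSB (1427 CPM against 15.9) and JUNB (496 against 18.8), a call lost by camera with an estimated correlation (adjusted p = 0.22). Ribosomal protein genes were higher for 38 of 40. In all, 1589 genes were higher and 1592 lower (2398 lower by limma-trend).

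Cluster 6 had high levels of DBH, the enzyme that makes noradrenaline, at 264 CPM ± 8.75 (SD, n = 2) against 0.293 in the other units (log2 fold change 9.90, SE 0.31, adjusted p = 3.5e-30). The adhesion genes NCAM2 (993 against 3.97) and CNTN5 (1666 against 6.09), the synaptic vesicle gene SV2C (126 against 0.559), SLC7A14 and FRMPD1 were also among the largest rises. HES1, a Notch target, had no count, at least 30.7-fold lower at the floor, and PTPN14 and ZFP36L1 were lower as well (0.919 against 84.9 and 2.76 against 166). Of 28 matrix genes 21 were lower and 2 higher (21 and 3 adjusted over the list alone), among them SPARC (10.6 CPM against 181), with an adjusted p = 0.026 with an estimated correlation. No cell-cycle gene was higher: 16 of 20 G2 and M genes and 12 of 20 S phase genes were lower (17 and 13 adjusted over the list alone), with adjusted p = 0.19 and adjusted p = 0.14 by camera with an estimated correlation. Of 40 ribosomal protein genes 31 were lower and 1 higher. Imprinted PEG10 stood at 709.7 CPM ± 34.2 against 175. In all, 1337 genes were higher and 1087 lower.

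Neuron-like cells were led by MGAT4C (547 CPM ± 47.5 against 1.58, log2 fold change 9.11, SE 0.18, adjusted p = 2.0e-38), the transcription factors ONECUT1 (166 against 0.704), EBF2 (157 against 1.06) and ST18 (124 against 1.60), the secretory granule gene SCG2 (158 against 2.54) and KLHL1. ADAMTS1, CCN2 and IGF2 showed the largest falls, IGF2 to 8.92 CPM against 108. Of 5 anterior HOX genes 4 were higher, also adjusted over the list alone, with HOXB2 at 123 CPM ± 11.9 against 27.6 and HOXA3 at 38.5 ± 9.90 against 5.07 (camera at the preset correlation adjusted p = 0.054). Of 28 matrix genes 23 were lower and 2 higher, also adjusted over the list alone, with adjusted p = 0.025 with an estimated correlation. S phase genes were lower for 18 of 20 and G2 and M genes for 14 of 20 (18 and 15 adjusted over the list alone), among them MKI67 (5.18 CPM against 32.3). By camera with an estimated correlation these had adjusted p = 0.11 and adjusted p = 0.22. Lower as well were 39 of 40 ribosomal protein genes, 22 of 27 oxidative phosphorylation genes (24 adjusted over the list alone, where 1 was higher) and 13 of 16 stress and dissociation genes. The camera calls of both of these lists were lost with an estimated correlation (adjusted p = 0.33 and 0.21). CRABP1, which binds retinoic acid, stood at 9999 CPM ± 6095 against 382, so the libraries differed in it. It is a leading gene of cluster 10, which made up 64 of 210 neuron-like cells in replicate 1 and 111 of 242 in replicate 2. In all, 1712 genes were higher and 1398 lower.

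Neural progenitor-like cells had higher levels of mitotic genes. CDK1, the kinase that drives entry into mitosis, stood at 61.4 CPM ± 0.424 against 6.04 (log2 fold change 3.84, SE 0.21, adjusted p = 4.4e-20), with STIL, KIF11, ASPM, KNTC1 and TTK between 61.5 and 123 CPM against 6.17 to 11.4. CDK1, STIL and ASPM are also leading genes of cluster 1, which held 312 of the 2082 cells pooled in this class. Of 20 G2 and M genes 18 were higher, and of 20 S phase genes 15, as also adjusted over the list alone, with adjusted p = 0.31 and adjusted p = 0.32 with an estimated correlation. WNT genes were higher for 13 of 16, also adjusted over the list alone, among them WNT3A (60.6 CPM against 18.2), with adjusted p = 0.14 with an estimated correlation. Notch and VEGF genes were higher for 13 of 17 and lower for 2, also adjusted over the list alone, among them HES1 (140.1 CPM against 39.8), without a camera call (adjusted p = 0.063). Energy genes were mostly lower. Of 27 oxidative phosphorylation genes 26 were lower, such as NDUFA4 (102 CPM against 367). Of 20 glycolysis genes 16 were lower, such as GAPDH (475 against 1197), and 2 higher. Both lists had the same counts adjusted over the list alone. With an estimated correlation these had adjusted p = 0.12 and adjusted p = 0.14. All 40 held-out ribosomal protein genes were lower too, with a median log2 fold change of -1.59. TPT1, UQCR11 and ATP6V0B showed the largest falls. These cells were shallow, with a median of 4470.5 UMI against 10215.5 in cluster 15. In all, 2585 genes were higher (1601 by limma-trend) and 1486 lower, and the median log2 fold change of all held-out genes was 0.24, which RLE factors moved by -0.11 to 0.12.

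Clusters 4, 13 and 15 shared higher levels of energy genes. In each, 25 of 27 oxidative phosphorylation genes were higher, also adjusted over the list alone. Of 20 glycolysis genes 16, 13 and 16 were higher, again also adjusted over the list alone, and 1 was lower in cluster 15. The adjusted p with an estimated correlation was 0.21, 0.21 and 0.21 for the former list in clusters 4, 13 and 15 and 0.11, 0.11 and 0.13 for the latter. All 40 ribosomal protein genes were higher in each as well. In cluster 9, 21 of 27 oxidative phosphorylation genes were higher too (adjusted p = 0.28 by camera with an estimated correlation). Of its 20 glycolysis genes 3 were higher and 7 lower. The units in the reference included neural progenitor-like cells, cluster 7 and neuron-like cells, where 26, 25 and 22 of the 27 were lower. In cluster 4 the largest rises were ADAMTS16 (108 CPM ± 17.3 against 5.13, log2 fold change 4.88, SE 0.24, adjusted p = 3.7e-22), PDZRN4, CORIN, CATHL5 and the axon guidance gene NTN1 (167 against 19.5). FRMD5, RSPO3 and CHN2 showed the largest falls, and RSPO3 lost its call among units of at least 50 cells (adjusted p = 0.095). Of 11 retinoic acid and hedgehog genes 4 were lower and 3 higher, also adjusted over the list alone, without a camera call (adjusted p = 0.10). GLI2, with no count, and HHIP (1.55 CPM against 36.9) were among the lower. WNT genes were lower for 8 of 16 and higher for 3 (9 and 3 adjusted over the list alone), with adjusted p = 0.12 with an estimated correlation. In all, 1509 genes were higher and 1057 lower in cluster 4.

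Cluster 15 was marked by WNT agonists. RSPO2 stood at 135 CPM ± 3.58 against 3.82 (log2 fold change 5.06, SE 0.21, adjusted p = 3.7e-25), RSPO3 at 529.9 ± 47.1 against 46.8 and RSPO1 at 48.6 ± 4.93 against 1.43, and the receptor FZD10 at 60.5 ± 2.78 against 5.85. Of 16 WNT genes 10 were higher and 1 lower, also adjusted over the list alone, with adjusted p = 0.11 with an estimated correlation. BMP and TGF-beta genes were higher for 9 of 14 and lower for 1, also adjusted over the list alone, among them ID3 (1023 CPM against 333), with adjusted p = 0.14 with an estimated correlation. MTTP, CATHL5 and PIWIL1 also rose, and FRMD5, DNM3 and CNTNAP2 fell. Cluster 13 had higher PTN, a secreted growth factor (593 CPM ± 6.43 against 54.8, log2 fold change 3.48, SE 0.11, adjusted p = 2.5e-30), SFRP2, a WNT antagonist (245 ± 49.3 against 25.2), TNNI3, PTPRZ1, CRABP1 and PHGDH, an enzyme of serine synthesis (519 ± 37.7 against 80.6). PLXNA4, CADPS and SUSD6 were lower. In clusters 15 and 13, 20 and 18 of 20 G2 and M genes were higher (20 and 20 adjusted over the list alone), with adjusted p = 0.18 and adjusted p = 0.19 with an estimated correlation. Totals were 1635 higher and 934 lower in cluster 15, and 1335 and 777 in cluster 13.

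Cluster 7 had higher GNG11, the testis genes TEX11 (152 CPM ± 10.2 against 7.07, log2 fold change 4.50, SE 0.21, adjusted p = 1.2e-22) and TEX15 (55.7 ± 11.4 against 4.81), ISG15, CNIH3 and CRTAC1. GNG11 differed between libraries, at 57.2 ± 61.4 against 1.37, and its log2 fold change was 2.47 without replicate 1. All 5 tested inflammation and interferon genes were higher, also adjusted over the list alone, with ISG15 at 53.1 ± 27.2 against 2.98 (camera at the preset correlation adjusted p = 0.10). Oxidative phosphorylation genes were lower for 25 of 27 and higher for 1. Glycolysis genes were lower for 16 of 20, among them LDHA (58.9 CPM against 288), and higher for 2. Both lists had the same counts adjusted over the list alone. By camera with an estimated correlation they had adjusted p = 0.16 and adjusted p = 0.14. All 40 ribosomal protein genes were lower. IGFBP5, KDELR1 and PRDX5 showed the largest falls. In all, 1953 genes were higher and 1473 lower. When units of at least 5 cells per library joined the fit, the genes lower in clusters 4, 6, 9, 13, 15 and neuron-like cells numbered 196, 571, 393, 167, 176 and 909, a drop of more than 1.5 times in each. With those small units 2451 of 5868 genes had a unit with no count, and none of these could be called lower where it was in the reference. That setting also ended the calls of 14 named falls, 13 of which met this limit (all but RSPO3), and no log2 fold change turned direction. PTPN14 in cluster 6 went from -6.45 to -5.38, and FRMD5, RSPO3 and CHN2 in cluster 4 from -3.66, -2.92 and -2.72 to -1.68, -2.20 (adjusted p = 0.15) and -1.17. PLXNA4 and CADPS in cluster 13 went from -4.46 and -3.30 to -2.86 and -1.13, and ADAMTS1 and IGF2 in neuron-like cells from -3.74 and -3.60 to -2.28 and -3.01. In cluster 15 FRMD5, DNM3 and CNTNAP2 went from -2.57, -2.51 and -2.24 to -0.70, -1.09 and -0.24. The others were CDH6, DZANK1 and PHACTR1, which have no count in cluster 9.

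**Figure D3:**
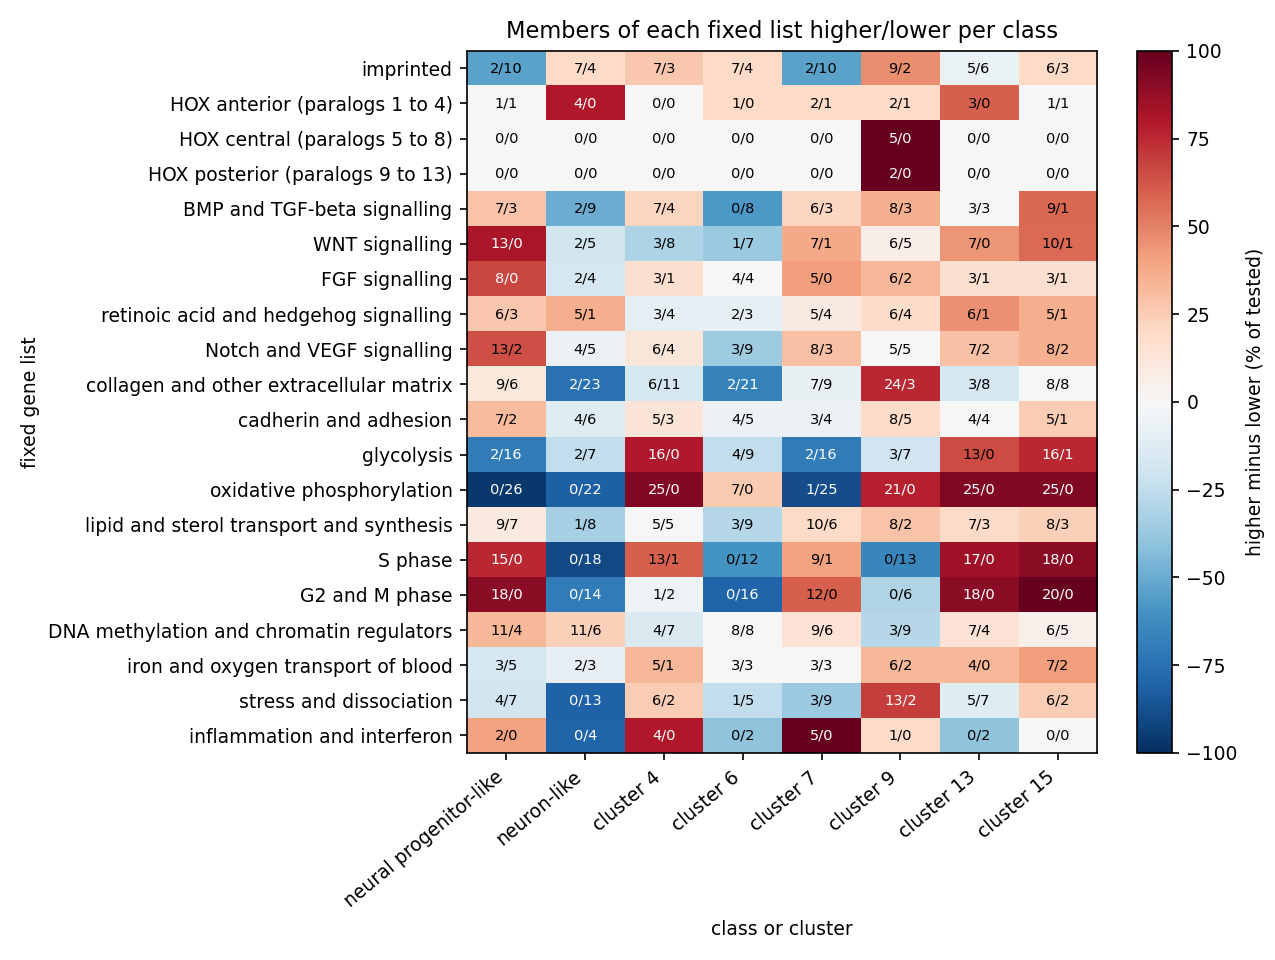
Members of each of 20 fixed gene lists that were higher/lower in each unit (numbers in cells) by edgeR's test, coloured by higher minus lower as a percentage of the members tested. Matrix genes are mostly higher in cluster 9 and mostly lower in neuron-like cells and cluster 6.

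The series title names extraembryonic differentiation, so trophoblast-like cells were set against embryonic classes. No extraembryonic class reached 20 cells per library, so this fit used a minimum of 5, chosen after seeing the data, with 7 and 10 trophoblast-like cells against cardiomyocyte-like, neural progenitor-like and neuron-like cells. PAGE4 stood at 14871 CPM ± 1742 (SD, n = 2) against 0.782 (log2 fold change 14.56, SE 0.26, adjusted p = 7.2e-72). PHLDA2, an imprinted gene known to restrain placental growth, stood at 5112 ± 1123 against 1.22 and the lysosomal protease CTSL at 3670.1 ± 2036 against 2.12. ITGB2, CD48 and IMPA2 also rose, though ITGB2 and CD48 lost their calls with DESeq2 (adjusted p = 0.17 and 0.20). MEIS2, GPC6 and SSBP2 had no count, at least 32.8-fold, 27.5-fold and 26.5-fold lower at the floor. All 27 oxidative phosphorylation genes were higher, also adjusted over the list alone, with NDUFA4 at 1608 CPM ± 246 against 231, and 38 of 40 ribosomal protein genes. In the reference classes neural progenitor-like and neuron-like, 26 and 22 of the 27 were themselves lower than in the other units, and no set test was run for this contrast. Of 16 imprinted genes 3 were higher and 8 lower (3 and 10 adjusted over the list alone), and of 20 chromatin regulators 2 were higher and 14 lower (2 and 15 over the list alone). GFP was lower (log2 fold change -4.35, SE 0.95, adjusted p = 0.0029). In all, 905 genes were higher and 1298 lower of 5868 tested, with 2887 lower by limma-trend.

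The 2 libraries were compared within each unit. Across 5913 genes, which are not independent replicates, log2 CPM correlated between libraries at r = 0.991 in neural progenitor-like cells and 0.924 in cluster 9, the lowest of the 8 units. The median absolute difference was 0.126 log2 units in neural progenitor-like cells, with 23 genes over 2-fold apart, and 0.403 in cluster 9, with 1250 such genes. Chi-square per gene, which sets the difference against counting error, was 3.52 in neural progenitor-like cells and 1.62 in cluster 9. For the same fold between libraries this value grows with the counts of a unit, so it does not rank units by agreement. It was highest in neuron-like cells, at 5.67. These comparisons carry no test.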

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

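The minimum of 5 cells, limma-trend, the limit of 3000 UMI, GFP without globin and the shares without clusters of almost 1 library were chosen after seeing the data. The fit was paired, with library as a term, and without that term all 81 named genes kept their calls. Numbered clusters could not be matched under another resolution or with doublets kept, so these settings were run for named classes only. Depth limits the classes with few cells: 4 to 22 cells per library for those of trophoblast and cardiomyocytes. The cause of each change below was not tested, except where a value is given for it.

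The share of the neural-list group was 85.2% with all barcodes, 86.8% at resolution 1.5 and 86.5% after centring, and 92.6% to 94.9% without 1 library. Neural progenitor-like cells were 45.7% with all barcodes, 54.8% with stricter filters, 46.3% with doublets kept, 54.3% and 57.7% at resolution 0.5 and 1.5, 62.8% with variable genes from all genes, and 70.1% to 70.2% without 1 library. Neuron-like cells were 8.32%, 5.93%, 5.64% and 4.44% with all barcodes, at resolution 1.5, with all genes and after centring. With all barcodes the mesenchyme list held 3.43%, trophoblast-like cells 0.492% and cardiomyocyte-like cells 0.710%. Trophoblast-like cells were 0.332% with stricter filters and 0.390% to 0.760% without 1 library. Cardiomyocyte-like cells were 1.08% with doublets kept, 1.80% at resolution 1.5 and 0% to 1.09% without 1 library. No binucleate trophoblast-like cells (0%) were named in either library alone.

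Genes lower in clusters 13, 15, 4, 6, 9 and neuron-like cells numbered 167, 176, 196, 571, 393 and 909 with units of at least 5 cells, where 90.6%, 91.1%, 89.8%, 74.0%, 80.6% and 69.5% of calls were higher, against 63.2%, 63.6%, 58.8%, 55.2%, 49.95% and 55.0%. With those units 2451 of 5868 genes had a unit with no count, against 537 of 5913, and no such gene could be called lower where that unit was in the reference. By limma-trend 2398 genes were lower in cluster 9 and 2887 in the extraembryonic contrast, and 1601 higher in neural progenitor-like cells. In neuron-like cells 680 genes were lower at resolution 1.5, with 67.2% of calls higher. Camera made 3 calls with an estimated correlation. Of the 81 named genes, 14 of 72 lost their call with units of at least 5 cells (13 of them with such a unit), none with limma-trend, 3 with DESeq2 and 1 of 63 with units of at least 50, and none reversed. Leaving out replicate 1 or replicate 2 moved 59 and 62 of the 81 by more than 1 SE, none of them across 0. The extraembryonic contrast could not run at 20 or 50 cells.

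For GFP, cluster 6 went to -0.0698, neural progenitor-like cells to -0.74 and neuron-like cells to -0.32 (log2) with units of at least 50 cells. With units of at least 5 cells neural progenitor-like cells went to 0.93, neuron-like cells to 1.53, cluster 6 to 1.74 and cluster 7 to -0.10. Neuron-like cells missed the threshold at 0.34 with no library term and at 0.38 with doublets kept. Without 1 library the range was 2.09 to 2.60 in cluster 4, -0.30 to 0.11 in neural progenitor-like cells and 0.18 to 0.48 in neuron-like cells. In cluster 7, cells of at least 3000 UMI gave 764 CPM. Without globin erythroid-like cells stood at 68.7 CPM. Thinning lowered the share of cells with a GFP UMI to 69.7% in the neural-list group, 84.7%, 93.9%, 97.2%, 82.2%, 58.4% and 7.03% in clusters 13, 15, 4, 6, 7 and 9, 59.6% in neural progenitor-like, 64.4% in neuron-like, 36.9% in cardiomyocyte-like and 8.06% in erythroid-like cells.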

Other observations

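The tests of the ratio of GFP to globin, of scaling, of globin in clusters 14 and 18 and of their depth were chosen only after the result was seen. Units too small for the report's fit were tested with a minimum of 5 cells per library, also chosen after seeing the data. The largest rises in cluster 19 (17 and 11 cells) were mixed: ATP6V1G3, a subunit of the proton pump, stood at 3273 CPM ± 694 (SD, n = 2) against 1.77 in the other units (log2 fold change 11.62, SE 0.21, edgeR adjusted p = 2.9e-71), the bicarbonate transporter SLC4A9 at 423 ± 80.5 against 0.0434, HEPACAM2 at 432 ± 167 against 0.358, NMB at 460.2 ± 110.2 against 0.830, EFHD1 at 72.7 ± 21.9 against 0.0565 and INCA1 at 146 ± 53.3 against 0.344. In erythroid-like cells the band 3 gene SLC4A1 stood at 147 ± 92.0 against 0.0638. Cluster 16c had higher HOXA5 (73.8 ± 20.0 against 0.812) and the retinoic acid enzyme ALDH1A2 (73.2 ± 65.2 against 0.866). Cardiomyocyte-like cells had higher BMP4 (89.0 ± 4.71 against 1.84) and HOXA6 (51.6 ± 6.86 against 0.527), while CXCL14 rested on 125 counts in replicate 2 and 1 in replicate 1.

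GFP was present at a low level in cluster 9, trophoblast-like and erythroid-like cells. Free RNA carried into droplets may account for it: the ratio of GFP to globin UMI in cluster 9 was 1.16 times that in trophoblast-like cells (95% interval 0.546 to 2.44), too wide an interval to decide. The UMI were not spread as depth alone would spread them. Their variance over cluster 9 cells was 2.89 times that of UMI dealt out by depth, at the smallest p that 10000 simulations can give. In trophoblast-like cells the variance was 2.31 times that of UMI dealt out by depth. A few reporter-expressing cells may also be present, although no cell of cluster 9 held more than 6 GFP UMI. The spread cannot tell such cells from free RNA, because the simulations took free RNA to follow depth, which was not measured. Droplets that held a neural cell as well would also give such a spread and stay open. No biological explanation was tested, since the design has 1 group.

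Oxidative phosphorylation transcripts were low in neural progenitor-like cells. In cells of 5000 to 8000 UMI the median log2 difference of the list was -1.05, against -1.04 over all cells, both without TMM factors. This band held 617 of 2082 neural progenitor-like cells and 15 cells of cluster 9. Depth does not account for the difference within the band, and cells outside it were not compared at matched depth. Scaling does not account for it as a whole cause, because a factor moves all genes alike. The list's median in the fit was -1.43. It lay at -1.67 from that of all held-out genes, with 27 of 27 members below it (SD over members 0.44). A loss of cytoplasmic RNA remains a candidate explanation, because the 40 held-out ribosomal protein genes fell with the list, with a median of -1.59 and 40 of 40 past the threshold. A lower output of both gene groups in these cells would look alike, and no biological explanation was tested.

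Clusters 14 and 18 each came from almost 1 library. Globin stood at no more than 0.441 times the highest level in another non-erythroid cluster of the same library. This argues against droplets that hold only free RNA if the globin of that other cluster is itself free RNA. The globin level of free RNA was not measured, so this point is not settled. Pairs of cells are argued against by depth, at no more than 0.621 times the library's median UMI, though pairs of shallow cells remain possible. A shift over the whole library is argued against by centring, after which 94.2% of their 138 cells still lay in clusters of almost 1 library. A difference in source or in how part of a sample was handled was not tested and stays open.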
